A study of Mus musculus with 4 samples.

How the data were processed

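The series measured RNA in naive CD4 T cells of mice by sequencing of rRNA-depleted total RNA. Per the labels' protocols, the cells were sorted by flow cytometry as TCRβ+ CD4+ cells with a naive surface phenotype that included CD25− and CD44-low, RNA was extracted with a micro-scale column kit, and libraries were made with the SMARTer Stranded Total RNA-Seq Pico Input kit, which starts from random priming and keeps strand. There were 4 libraries, 2 from wild-type mice (WT) and 2 from double-knockout mice (DKO). The WT mice were littermates that carried loxP-flanked Btg1 and Btg2 without the recombinase. The DKO mice carried the same alleles with Cre expressed from Cd4 regulatory sequences, which deletes them in the T cell lineage. Groups and replicate numbers were taken from the sample titles and genotype labels. The labels speak of pairs of WT and DKO mice, so the libraries of a group were treated as separate animals.

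Abundances had been estimated by the authors with kallisto, and the builds mm10 and GRCm38 are named, per the submitters' processing notes. The kallisto version, its strand setting and the annotation release are not given in the sources used here. The deposited values comprise, per the file headers, estimated counts per transcript, which are not scaled for depth or length. They further comprise TPM, scaled by the authors for effective length and to a common sum per library, per the file headers. The deposited effective length in bases has 1 value per transcript and library, per the file headers. Estimated counts divide reads that fit several transcripts, so near-identical genes share reads, and without a stated strand setting reads of overlapping antisense genes cannot be told apart.

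Each file listed 126782 transcripts. Of these, 125182 (98.7%) were joined by identifier, without version, to GENCODE mouse release M21 on GRCm38, and 97.1% of the lengths equalled those of that release. The 1600 transcripts without a gene held 0.846% of the WT and 0.827% of the DKO counts on average and were left out of the gene tests. Estimated counts were summed to 48858 genes and rounded to whole numbers. Total estimated counts were 14970076 and 13889894 in the WT and 16567226 and 17827631 in the DKO libraries. Of these, 37.3 ± 2.26% in WT and 46.8 ± 2.98% in DKO (SD, n = 2 each) fell on genes annotated as protein-coding. At 3 counts, taken as the floor, a gene had 0.2, 0.216, 0.181 and 0.168 CPM of the library total in the same order. The libraries carry no molecular identifiers that were used here, so intervals and floors cover counting error only.

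Genes were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM factors, robust dispersion estimates and the quasi-likelihood F test on genotype, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. After the filter 12863 genes were tested, 10733 of them protein-coding. The common biological coefficient of variation was 0.2195. Standard errors (SE) are the fold change divided by the square root of F. CPM values given per library use TMM-scaled library sizes, and log2 fold changes are DKO minus WT. Before the data were examined, 42 gene lists were written for T cell states, signalling, metabolism, translation, RNA decay and other cell types that a sort could hold, and 39 with at least 5 tested members were tested with camera in limma 3.58.1. Camera used a preset correlation between genes of 0.01 on log2 CPM with a prior count of 2, with Benjamini-Hochberg adjustment over the lists. The lists for NK and innate lymphoid cells, stroma and endothelium, and sex-linked genes had 3, 2 and 4 tested members and were not tested. Symbols missing from the annotation were looked up by synonym, which resolved 6.

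The genes named in the text were chosen by a rule written before the data were examined. It takes Btg1 and Btg2, then up to 10 called protein-coding genes in each direction with a mean of at least 5 CPM and no overlap between the groups. It adds up to 4 members with the smallest unadjusted p of each list past the threshold, 16 fixed readouts of T cell state, and the most abundant member of each list of other cell types. That gave 76 genes, of which 1 fixed readout is not reported here. Non-coding genes and single list members outside the rule are marked as chosen after their values were seen.

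The functions were first tested on simulated counts for 12320 genes with the means, depths and dispersions of the libraries. Of genes changed by a log2 fold of 1, 36 of 68 (52.9%) were called in the right direction, against 63 of 66 (95.5%) at 2 and 65 of 66 (98.5%) at 4. Of 12120 unchanged genes, 5 were called, and none of the 39 unchanged lists was called by camera. The changed genes were drawn from those above a minimum mean count, so these rates do not cover weakly expressed genes. Simulated genes varied independently, whereas the cytosolic ribosomal protein list had an estimated correlation of 0.88 in the real libraries. The simulation therefore does not show how often camera calls lists whose genes vary together.

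TMM assumes that most genes do not change, so a change in total mRNA per cell cannot show in these fold changes. No spike-in was used here. The alternatives comprised other scalings and count filters, DESeq2 1.42.0, voom, TPM with pseudocounts of 1 and 0.1, an effective length offset, a replicate block, thinned counts, a threshold of 0.1, transcripts as units, other list tests and leaving out each library. Scaling to 5 RNA polymerase III transcripts, trend removal by length or GC content, other edgeR defaults and a test of protein-coding genes alone were added after the data had been seen. Figures and further summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.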

Results

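The libraries compared naive CD4 T cells with and without BTG1 and BTG2, related proteins that bind the CCR4-NOT deadenylase complex, which shortens poly(A) tails. The question, from the title of the series, was which RNAs change when both genes are removed from resting T cells. There were 2 WT and 2 DKO libraries with 13889894 to 17827631 estimated counts each. With 2 against 2, an exact two-sided permutation test cannot give a p below 0.333, so single values are given with their SD and the p-values come from models fitted across genes.

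Both targets were almost gone from the DKO libraries. Btg1 (ENSMUSG00000036478, chromosome 10, 96617006 to 96622809, plus strand) fell from 500 ± 42.2 CPM in WT to 5.92 ± 0.207 CPM in DKO (SD, n = 2 each), a log2 fold change of −6.40 (SE 0.19). Its estimated counts were 7378 and 5443 in the WT and 103 and 125 in the DKO libraries. Btg2 (ENSMUSG00000020423, chromosome 1, 134075170 to 134079120, minus strand) fell from 92.5 ± 0.594 to 0.309 ± 0.0204 CPM, with counts of 1295 and 1067 against 5 and 7 and a log2 fold change of −8.18 (SE 0.21). The DKO level was 1.18% of WT for Btg1 and 0.33% for Btg2. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 1.43e-06 for Btg1 and 8.76e-07 for Btg2. The deleted exons are not given in the sources used here, and counts cover whole transcripts.

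The DKO libraries held a larger share of nuclear protein-coding RNA and smaller shares of several short structural RNAs. Protein-coding genes other than mitochondrial genes and Lars2 took 30.5 ± 0.191% of the counts in WT and 37.9 ± 3.47% in DKO (SD, n = 2 each), with 30.7 and 30.4% against 35.4 and 40.4% per library. Small nucleolar RNAs, which guide rRNA modification, took 0.697 ± 0.322% and 0.301 ± 0.099%. Small nuclear RNAs of the spliceosome took 0.389 ± 0.088% and 0.17 ± 0.013%, and mitochondrial tRNAs 0.124 ± 0.054% and 0.042 ± 0.014%. The annotated rRNA gene CT010467.1, which need not hold all cytosolic rRNA left by the depletion, took 30.7 ± 2.20% and 23.5 ± 3.28%. A set of 5 RNA polymerase III transcripts (Rn7sk, Rn7s1, Rn7s2, Rmrp and Rpph1) took 1.67 ± 0.359% and 1.10 ± 0.107%. In each of these classes the libraries of WT and DKO did not overlap, whereas they did for mitochondrial rRNA (7.92 ± 1.38% and 7.63 ± 0.419%) and mitochondrial mRNA (1.08 ± 0.285% and 0.976 ± 0.082%). They also overlapped for the rRNA-like genes Gm42418 and Gm26917 (6.31 ± 1.17% and 6.90 ± 0.308%). Another 9.26 ± 0.007% and 8.95 ± 0.352% lay on 3 genes of 57 bases annotated as miRNAs (Gm24245, Gm23935 and Gm24270), without overlap between the groups. Lars2 was kept apart as a single gene with 5.63 ± 1.79% of the counts in WT and 7.91 ± 0.57% in DKO. Of its counts, 99.98% lay in 1 transcript. The origin of these reads was not tested, so its share is uncertain.

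**Figure D1:**
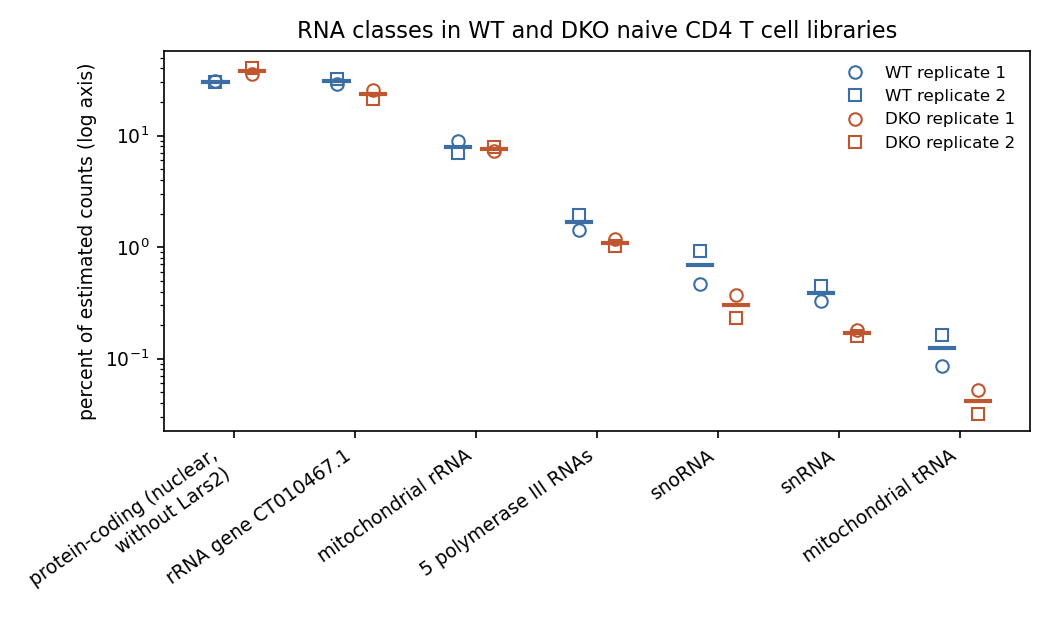
Share of estimated counts in each RNA class, in percent on a log axis, for each WT (blue) and DKO (orange) library, with bars at the group means. Nuclear protein-coding RNA lay at 30.7 and 30.4% in WT and 35.4 and 40.4% in DKO, while snoRNA, snRNA and mitochondrial tRNA lay lower in both DKO libraries.

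The ratio of nuclear protein-coding to RNA polymerase III counts, on the log2 scale, was 4.44 and 3.98 in WT and 4.92 and 5.31 in DKO, a difference of 0.90 or 1.87-fold against a pooled SD of 0.299. The same difference was 0.35 against mitochondrial rRNA (pooled SD 0.177), 0.70 against CT010467.1 (0.250), 1.49 against snRNA (0.294) and 1.48 against snoRNA (0.660). It was −0.01 against Malat1, a nuclear long non-coding RNA, and 0.17 against the rRNA-like genes Gm42418 and Gm26917, with overlapping libraries in both. The difference lay between 0.67 and 1.13 when each library was left out in turn. The implied mean fragment length also differed, at 121.8 ± 2.8 bases in WT and 137.8 ± 6.2 bases in DKO (SD, n = 2 each).

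Under TMM scaling and apart from the targets, 5 protein-coding genes rose in DKO and none fell. With the targets included, the protein-coding calls were 5 higher and 2 lower, against 183 and 5 with total counts, 447 and 2 when scaled to the polymerase III transcripts and 35 and 16 when protein-coding genes were tested alone. Prg4, which encodes the secreted lubricating proteoglycan lubricin, rose 4.15-fold from 3.53 ± 0.594 to 14.7 ± 0.397 CPM. Ms4a4c, of the membrane-spanning MS4A family, rose 3.11-fold from 5.48 ± 0.0624 to 17.1 ± 3.30 CPM. Ddit4, whose stress-induced product restrains mTORC1, rose 2.91-fold from 10.7 ± 0.342 to 31.2 ± 5.94 CPM. Art2b, a cell-surface ADP-ribosyltransferase of T cells, rose 2.39-fold from 12.9 ± 1.70 to 30.97 ± 1.75 CPM, and Dapl1, a transcript of naive T cells, rose 2.33-fold from 59.2 ± 10.6 to 138 ± 0.109 CPM (SD, n = 2 each for all).

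At an unadjusted p below 0.05, 471 protein-coding genes were higher and 286 lower by edgeR. At its own adjusted threshold of 0.05, DESeq2 called 55 genes of any type higher and 133 lower. The log2 fold changes were 2.05 (SE 0.23) for Prg4, 1.64 (0.22) for Ms4a4c, 1.54 (0.18) for Ddit4, 1.26 (0.16) for Art2b and 1.22 (0.16) for Dapl1. Their adjusted p-values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.0299, 0.0384, 0.0357, 0.0384 and 0.0384. On GRCm38, Prg4 lies on chromosome 1 (150449412 to 150466165, minus strand) and Ms4a4c on chromosome 19 (11404770 to 11427246, plus strand). Ddit4 lies on chromosome 10 (59949669 to 59951834, minus strand), Art2b on chromosome 7 (101576970 to 101585600, minus strand) and Dapl1 on chromosome 2 (59484653 to 59505020, plus strand). Ms4a4c and Art2b have close paralogues, so their estimated counts are uncertain where reads fit both copies. The calls of all 5 ended in both TPM fits, with an effective length offset and with transcripts as units, and those other than Prg4 ended when the GC trend was removed. Their log2 fold changes stayed at 1.28 to 2.19 with the offset (adjusted p = 0.0508 to 0.105 by edgeR) and the 4 at 1.22 to 1.74 without the GC trend (adjusted p = 0.0570 to 0.0864), so these losses do not show that length or GC content made the changes. Without DKO replicate 1, Art2b (log2 1.22, adjusted p = 0.0933) and Dapl1 (1.24, adjusted p = 0.0548) did not pass edgeR's test.

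**Figure D2:**
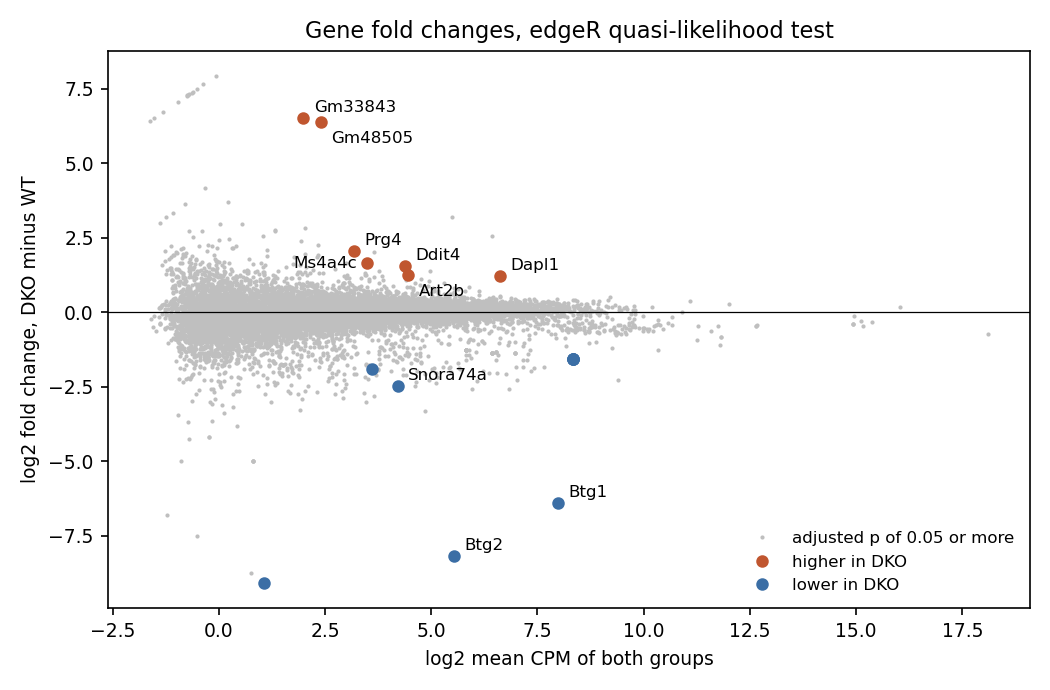
Log2 fold change (DKO minus WT) against the log2 mean CPM of both groups for 12863 tested genes, with called genes in orange (higher) and blue (lower). Btg1 and Btg2 lie at −6.40 and −8.18, and the 5 called protein-coding genes above the axis lie between 1.22 and 2.05; fitted values of genes with almost no counts in 1 group depend on the prior count.

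Over all gene types 7 genes were higher and 9 lower by edgeR's quasi-likelihood test, against 492 and 560 at an unadjusted p below 0.05. The split moved with the scaling, from 43.8% higher among the TMM calls to 194 higher and 66 lower (74.6%) with total counts only and 472 higher and 22 lower (95.5%) when scaled to the polymerase III transcripts. The median of all genes was −0.01, 0.33 and 0.90 under these 3 scalings, and 97.6% of protein-coding genes lay above 0 in the last. Without WT replicate 1, WT replicate 2, DKO replicate 1 or DKO replicate 2, the calls were 34 and 131, 30 and 50, 15 and 37, or 12 and 28.

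The other called genes were non-coding and were chosen for description after their values were seen. The long intergenic RNAs Gm33843 (chromosome 10, 96519157 to 96595731, minus strand) and Gm48505 (96495721 to 96523982, minus strand) lie 21.3 and 93.0 kb upstream of Btg1 and overlap each other. Gm33843 had 2 and 0 counts in WT and 123 and 184 in DKO, a ratio of 101.3 (exact 95% interval 27.8 to 840.3) with adjusted p = 0.0157 by edgeR. Gm48505 had 1 and 2 counts in WT and 114 and 308 in DKO, a ratio of 92.8 (31.6 to 452.0) with adjusted p = 0.0168 by edgeR. The processed pseudogene Gm8601, 139.6 kb upstream on the plus strand, had 0 and 0 against 22 and 39 counts, at least 13.4-fold higher over a floor of 3 counts in the WT group, and did not pass the test (adjusted p = 0.162 by edgeR).

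**Figure D3:**
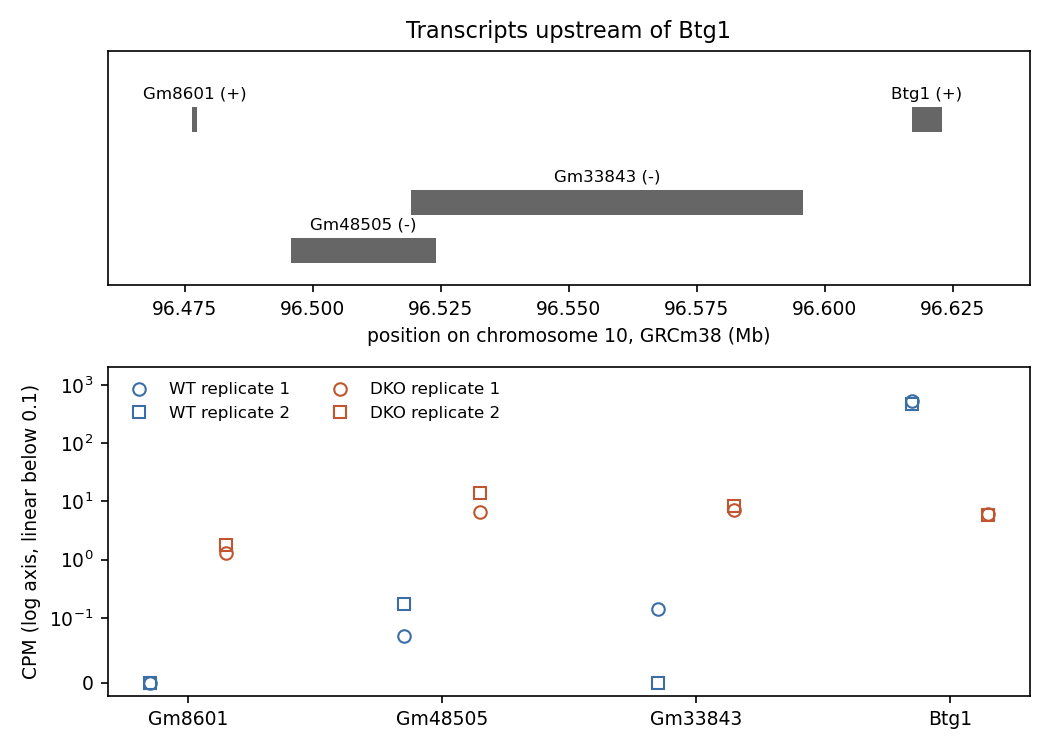
Top, positions of Gm8601, Gm48505, Gm33843 and Btg1 on chromosome 10 of GRCm38 in Mb, with strands; bottom, CPM in each WT (blue) and DKO (orange) library on a log axis that is linear below 0.1. The 3 upstream genes had 0 to 2 counts in each WT library and 22 to 308 in each DKO library.

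Among lower non-coding genes, 4 copies of the U2 spliceosomal RNA (Gm24950, Gm23971, Gm23849 and Rnu2-10) had identical counts in every library, since they share reads, and together count as 1 result, which fell from 487 ± 108 to 163 ± 29.5 CPM per copy. Snora74a, a nucleolar guide RNA, fell from 31.4 ± 6.06 to 5.72 ± 2.08 CPM, a log2 fold change of −2.47 with adjusted p = 0.0308 by edgeR. The Cajal body RNA Gm26083 fell by 1.89 on the log2 scale. Most snoRNAs and snRNAs lay in the same direction, with both DKO libraries below both WT libraries for 141 of 196 and 66 of 81 tested genes (chance gives 16.7% for a single gene) and a median log2 fold change of −1.64 in each class. With genes of identical counts taken once, as they share reads, these were 138 of 190 and 49 of 61. The pseudogene Gm10705 had 67 and 41 counts in WT and none in DKO, but 90.5% of its 31-base words occur in Ube2l3, so its call is uncertain.

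Of the 39 lists, 11 were higher and 3 lower in DKO by camera, against 13 and 3 at an unadjusted p below 0.05. With an estimated correlation in place of the preset one, 0 lists passed in either direction (0 and 1 at an unadjusted p below 0.05), the lowest adjusted p being 0.646. The rotation test fry called 0 higher and 1 lower (7 and 1 unadjusted), the BTG-TOB and deadenylase list with adjusted p = 0.0106, which holds both targets. Fry's mixed test, which counts changes in either direction, passed 4 lists. These were the BTG-TOB list (adjusted p = 0.00119), TCR signalling (0.0161), CD8 T cells (0.0161) and histones (0.0221). Over all genes tested, the called list members were Btg1, Btg2, Ddit4 and Dapl1. Without WT replicate 1, 4 lists were higher, and the naive, anergy, p53, TCR signalling, JAK-STAT, trafficking, CD8 T cell and snoRNA host lists did not pass. The effector list did not pass without WT replicate 2 or DKO replicate 2, the cholesterol list without WT replicate 2, the JAK-STAT list without DKO replicate 1, and the naive and anergy lists without DKO replicate 2, while 6 lists were lower without DKO replicate 1. The effector list also lost its call with total counts and in both TPM fits, and the JAK-STAT list in 6 further settings, among them the replicate block and protein-coding genes only. List medians are log2 fold changes under TMM.

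Transcripts of regulatory T cells were higher in DKO. The list had 14 tested members with a median of 0.85 (camera adjusted p = 2.83e-09; adjusted p = 0.646 with an estimated correlation). Both DKO libraries lay above both WT libraries for 13 members, and 9 passed when adjusted over the list alone, 0 over all genes. Nrp1, a surface receptor of thymus-derived regulatory T cells, was at 0.977 ± 0.649 CPM in WT and 7.19 ± 2.50 CPM in DKO (log2 2.84, adjusted p = 0.0943 by edgeR). Foxp3, which specifies these cells, was at 1.79 and 2.50 CPM against 5.12 and 10.4 CPM (log2 1.87), and Ikzf2, encoding Helios, had a log2 fold change of 1.65. Il2ra, encoding the CD25 that the sort excluded, was at 1.24, and Izumo1r, a folate receptor family member, at 0.84. Ctla4, an inhibitory receptor of the same list chosen after its values were seen, was at 3.37 and 3.54 against 3.18 and 3.97 CPM (log2 0.05). Over all genes, edgeR called Nrp1 (log2 3.18), Ikzf2 (2.05) and Foxp3 (2.30) without DKO replicate 1, Nrp1 (3.78) without WT replicate 1 and Izumo1r (1.15) without WT replicate 2.

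**Figure D4:**
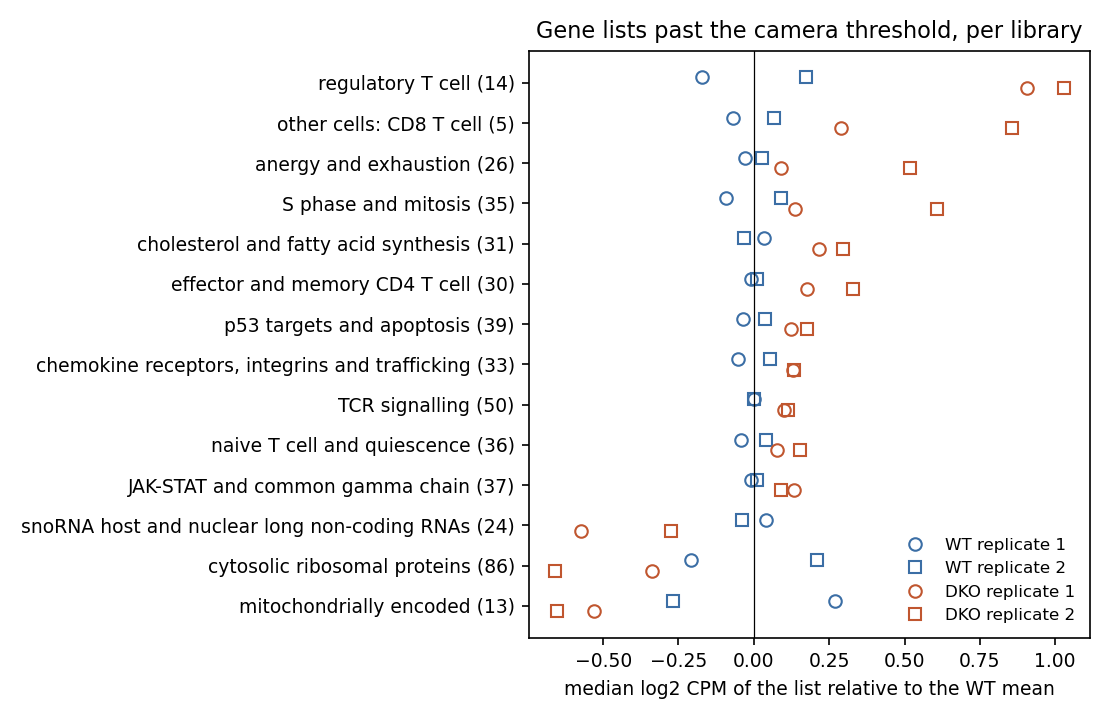
Median log2 CPM of each list past the camera threshold relative to the WT mean, for each WT (blue) and DKO (orange) library, with the number of tested members in parentheses. The regulatory T cell list lay at 0.91 and 1.03 in DKO, while the S phase and mitosis list lay at 0.14 and 0.61.

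Other T cell lists were higher by smaller amounts. The effector and memory list (30 members, median 0.17, camera adjusted p = 0.0247; adjusted p = 0.783 with an estimated correlation) had 3 higher and 0 lower when adjusted over the list alone and 0 over all genes. Those were Cd44, the activation marker gated low in the sort (log2 0.86), Izumo1r and Il2rb, a receptor chain for IL-2 and IL-15 (1.02). The anergy and exhaustion list (26, median 0.35, adjusted p = 0.00252; adjusted p = 0.646 with an estimated correlation) had Izumo1r alone past the test adjusted over the list alone and 0 over all genes, with Egr2 at 0.93, Egr3 at 0.997 and Btla at 0.65. The CD8 T cell list (5, median 0.60, adjusted p = 0.00548; adjusted p = 0.646 with an estimated correlation) had 2 higher adjusted over the list alone and 0 over all genes, the protease Ctsw (1.19) and the NK receptor chain Klrd1 (1.17), with Cd8b1 at 0.60 and Runx3 at 0.12. Prf1, the remaining tested member of the CD8 T cell list, added after its values were seen, was at 0.009. Without DKO replicate 2, Cd8b1 was at 0.295 and the anergy median relative to all tested genes at 0.13 in place of 0.36 (0.21 without WT replicate 1). The effector median was 0.35 in place of 0.18 without WT replicate 2.

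The naive and quiescence list lay slightly higher as a whole (36 members, median 0.10, camera adjusted p = 0.0247; adjusted p = 0.783 with an estimated correlation). Dapl1 was higher and Klf6 (log2 −0.63) lower when adjusted over the list alone, and over all genes Dapl1 alone passed. The naive cell regulators Klf2 (0.01), Foxo1 (−0.04), Foxp1 (0.09) and Tcf7 (−0.12) and the homing receptor Ccr7 (0.10) did not pass the test. Klf2, Foxo1, Foxp1 and Tcf7 overlapped between the groups, as did the activation marker Cd69 (0.12) and Myc (−0.08). Egr1 was at 0.52, Ccnd2 at 0.34, Il7r at 0.45 and the ubiquitin ligase gene Peli1 at 0.40. Egr1 was at 0.30 without WT replicate 1 and 0.78 without WT replicate 2, and the list median relative to all tested genes at 0.06 and 0.20.

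Signalling and trafficking lists also lay slightly higher. TCR signalling (50 members, median 0.11, camera adjusted p = 0.00352; adjusted p = 0.646 with an estimated correlation) had 0 members past the test adjusted over the list alone or over all genes by edgeR and both DKO libraries above both WT for 19, with Pag1 (0.42), Cblb (0.41), Nck1 (0.48) and Stim2 (0.36). JAK-STAT (37, 0.09, adjusted p = 0.0277; adjusted p = 0.646 with an estimated correlation) had 3 higher adjusted over the list alone and 0 over all genes, Ifngr1 (0.69), Il2rb and Il10ra (1.14). Chemokine receptors, integrins and trafficking had 33 members and a median of 0.13 (camera adjusted p = 0.00352, or 0.646 with an estimated correlation). Cd44 and Gpr18 (0.73) were the 2 higher adjusted over the list alone, and 0 passed over all genes. The receptor genes S1pr1 and S1pr4 were at 0.38 and 0.49. S1pr4 was at 0.26 without WT replicate 1 and 0.78 without WT replicate 2. Without WT replicate 2 the medians relative to all tested genes were 0.19 for TCR signalling, 0.20 for JAK-STAT and 0.22 for trafficking.

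Survival, lipid and cell cycle lists were also higher. The p53 and apoptosis list (39, median 0.14, adjusted p = 0.00252; adjusted p = 0.646 with an estimated correlation) had Ddit4 alone past the test, adjusted over the list alone and over all genes, with Trp53inp1 at 0.73, the pro-apoptotic Bbc3 at 0.91 and the anti-apoptotic Bcl2 at 0.47. Cholesterol and fatty acid synthesis (31, 0.26, adjusted p = 0.00260; adjusted p = 0.646 with an estimated correlation) had 0 members past the test adjusted over the list alone or over all genes by edgeR, with Sc5d at 0.81, Dhcr7 at 0.51, Insig2 at 0.84 and Srebf1 at 0.39 (0.25 without WT replicate 1). The medians relative to all tested genes were 0.26 in place of 0.15 for the p53 list without WT replicate 2 and 0.175 in place of 0.27 for the cholesterol list without WT replicate 1. S phase and mitosis (35, 0.33, adjusted p = 0.000297; adjusted p = 0.703 with an estimated correlation) also had 0 past the test on either adjustment, and both DKO libraries above both WT for 14. Its per-library medians were 0.14 in DKO replicate 1 and 0.61 in DKO replicate 2, with Hmgb2 at 0.87, Top2a at 7.39 and 5.61 against 9.54 and 21.4 CPM and Mki67 at 4.24 and 5.78 against 8.89 and 31.3 CPM. Without DKO replicate 2 the log2 fold change of Top2a was 0.57 in place of 1.25 and the list median relative to all tested genes 0.15 in place of 0.34, and that of Lig1 was 0.43 without WT replicate 1 and 1.04 without WT replicate 2 in place of 0.70.

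The lower lists held ribosomal and mitochondrial transcripts and hosts of snoRNAs. Scaled to the polymerase III transcripts, their medians stayed below the 0.90 of all genes. That scaling moves all genes by nearly the same amount, so the place of a list relative to all genes could hardly change. It is no separate test of these lists. Cytosolic ribosomal proteins (86 members) had a median of −0.52 under TMM and 0.42 under that scaling (camera adjusted p = 9.46e-17; adjusted p = 0.783 with an estimated correlation), with Rpl12 (−0.99) and Rpl5 (−1.15) past the test adjusted over the list alone and 0 over all genes. Both DKO libraries lay below both WT for 60 of the 86, Rpl31 (−0.65) and Rps18 (−0.70) among them. The ribosomal median relative to the WT mean was −0.21 and 0.21 in WT replicates 1 and 2 and −0.34 and −0.66 in DKO. In each group it was lower in the library with longer fragments, a length difference that also runs with genotype. Length and genotype therefore cannot be told apart for this list. In WT, the mitochondrial (0.27 and −0.27) and snoRNA host (0.04 and −0.04) list medians went the other way. Mitochondrially encoded genes (13) had a median of −0.63, or 0.21 under that scaling (adjusted p = 1.53e-05; adjusted p = 0.646 with an estimated correlation), with 10 lower adjusted over the list alone and 0 over all genes, mt-Nd6 (−0.88), mt-Nd2 (−0.71) and mt-Nd5 (−0.68) among them. The snoRNA host and nuclear non-coding RNA list (24) had a median of −0.48, or 0.41 under that scaling (adjusted p = 7.63e-05; adjusted p = 0.646 with an estimated correlation), with 5 lower adjusted over the list alone and 0 over all genes, including Snhg17 (−1.18) and Zfas1 (−1.10), with Gas5 at −0.56. Relative to all tested genes, the ribosomal median ranged from −0.73 without WT replicate 1 to −0.28 without WT replicate 2 and the mitochondrial one from −0.30 without WT replicate 1 to −0.88 without WT replicate 2, passing camera's test each time. The snoRNA host median was −0.31 without WT replicate 1, where mt-Nd6, mt-Nd2 and mt-Nd5 were at −0.53, −0.42 and −0.43.

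The remaining 25 lists did not pass, with camera adjusted p from 0.0886 to 0.990. The BTG-TOB and deadenylase list had a median of −0.05 (23 members), with Tob1, a related antiproliferative gene, at 0.59. Tob1 passed the test adjusted over the list alone beside both targets, which alone passed over all genes, and Cnot7, a deadenylase subunit, was at −0.23. mRNA decay factors (47) had a median of −0.01, mTORC1 and amino acid transport (36) 0.08, glycolysis (25) 0.02, nuclear-encoded OXPHOS (74) −0.10, translation factors (59) −0.06, ribosome biogenesis (43) −0.04 and tRNA synthetases (17) 0.03. The proteasome (43) was at 0.04, autophagy and lysosome (41) at 0.06, the unfolded protein response (25) at 0.03, heat shock proteins (21) at 0.12, splicing factors (50) at −0.02 and chromatin regulators (57) at 0.06. G1 cyclins and inhibitors (27) were at −0.00, GIMAP GTPases (8) at −0.04, Zfp genes (314) at −0.02, T cell receptor variable segments (86) at −0.02 and histones (55) at 0.09. The type I interferon list (47) was at 0.01 and the immediate early list (46) at −0.08. Adjusted over the list alone by edgeR, 6 immediate early genes were higher and 4 lower, 2 and 2 histones (adjusted p = 0.0221 in fry's mixed test), 1 GIMAP gene higher and 1 interferon gene lower. None of these passed over all genes, and Ddit4 alone passed in the mTORC1 list on both adjustments. Relative to all tested genes, camera called the interferon (0.40), proteasome (0.22) and histone (0.345) lists higher without WT replicate 2, the histone list (0.345) also without DKO replicate 1, and the tRNA synthetase (0.30), mTORC1 (0.15) and heat shock (0.30) lists without DKO replicate 2. It called OXPHOS lower without WT replicate 1 (−0.31) or DKO replicate 1 (−0.15) and translation factors without DKO replicate 1 (−0.09). Lists called after a change of sign are not named here, so the number of lists called without a library can exceed those named. Such changes were large for some lists. The relative median ranged from −0.278 to 0.304 for tRNA synthetases and from −0.311 to 0.173 for OXPHOS. Median, mean and camera direction differed in sign for the interferon, GIMAP, Zfp, variable segment, mRNA decay, unfolded protein, immediate early, and erythroid and platelet lists.

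Of the lists of other cells, only the CD8 T cell list (median 0.60) passed camera's test with the preset correlation (adjusted p = 0.00548; adjusted p = 0.646 with an estimated correlation). It did not pass without WT replicate 1 (adjusted p = 0.0651 by camera) or without a count filter (0.0564). Medians of the rest were 0.12 for B cells (6 members), 0.19 for myeloid and dendritic cells (11), −0.04 for erythroid cells and platelets (5) and 0.21 for thymocytes and recent emigrants (11, the lowest adjusted p of these, 0.0886 by camera). Without DKO replicate 1 the myeloid list (0.45 relative to all tested genes, adjusted p = 0.0391) and the thymocyte list (0.19, adjusted p = 0.0420) passed camera's test, while the myeloid value was 0.03 without DKO replicate 2 and the thymocyte value 0.125 without WT replicate 2. The most abundant members of these lists and of the untested NK and stromal lists did not pass the test, with the immunoglobulin gene Ighm at 138.9 and 181.1 against 162.5 and 145.6 CPM per library. Group levels in CPM were 81.0 ± 17.3 and 83.2 ± 9.32 for the myeloid protease gene Ctss, with Bpgm at 9.49 ± 1.35 and 9.23 ± 0.398, Satb1 at 668 ± 4.88 and 709 ± 18.7, Rora at 5.93 ± 2.78 and 4.52 ± 1.06 and Pecam1 at 147 ± 20.7 and 134 ± 9.60 in WT and DKO. Satb1 also stands in the naive list, and Rora and Runx3, the most abundant of the CD8 T cell list, in the effector list. Such genes can come from the sorted T cells themselves, so their levels are no test of other cells in the sort.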

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

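The tests on rRNA depletion, on a single outlying library and on regulatory T cells were chosen only after the result was seen. The effective length values, which entered only alternative fits, as an offset or through the TPM values, imply a mean fragment length of 133.5 bases in DKO replicate 1 and 142.2 bases in DKO replicate 2, above the 123.8 and 119.8 bases of the WT libraries. This difference runs with genotype in all 4 libraries, so no comparison of WT with DKO libraries separates it from the knockout. Within each group, the library with longer fragments also had the smaller snoRNA share, 0.469 against 0.925% in WT and 0.231 against 0.371% in DKO. That library's log2 ratio of protein-coding to polymerase III counts was higher, 4.44 against 3.98 in WT and 5.31 against 4.92 in DKO. The ratio to mitochondrial rRNA was higher in DKO (2.35 against 2.27) but lower in WT (1.79 against 2.13). With 2 libraries per group, this does not show that length was the cause.

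The DKO libraries held more nuclear protein-coding RNA relative to structural RNAs. More complete rRNA depletion would raise protein-coding and polymerase III RNAs alike, whereas their log2 ratio differed by 0.90, over 2 times its pooled SD of 0.299, which argues against depletion as the whole cause. Longer fragments could lose short RNAs, and protein-coding genes with transcripts of at most 600 bases lay −0.1 from those over 2000 bases (95 and 1692 genes). On the same measure, 34 histones among the short genes lay at 0.074, 9 ribosomal protein genes at −0.557 and 52 others at −0.115. The bound for the pooled value, set beforehand, counts against a length effect. However, the same difference was 0.405 between the WT and −0.016 between the DKO libraries. The structural RNAs are also shorter than most of these mRNAs, so length and genotype cannot be told apart. A larger mRNA content of cells without BTG1 and BTG2 is a hypothesis that stays open and untested, since no external standard was used here.

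Gm33843 and Gm48505, upstream of Btg1, were nearly absent in WT and present in both DKO libraries. Reads shared with other genes are argued against, since at most 5.0% of the 31-base words of either transcript occur in transcripts of other genes. A change across the neighbourhood may be involved, because the median absolute log2 fold change of the 6 other tested genes within 1 Mb was 0.55, above the bound of 0.5 set beforehand. That median is smaller than the median SE of 1.01 of these genes, a condition added after the value was seen, so it cannot be told apart from noise. Apart from Gm8601, at 139.6 kb, these genes lie 571.5 to 984.8 kb from Btg1, so their median says little about the nearer region. There Gm8601 had 0 and 0 counts in WT and 22 and 39 in DKO (adjusted p = 0.162 by edgeR), in the same direction as Gm33843 and Gm48505. Within 1 Mb of Btg2, 0 of 19 tested genes were called by edgeR and 2 had an unadjusted p below 0.05, and an effect of the recombined Btg1 allele on transcripts nearby was not tested.

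The regulatory T cell list passed camera's test with the preset correlation, but not with an estimated one (adjusted p = 0.646) or by fry (adjusted p = 0.219), and 0 of its 14 tested members passed over all genes by edgeR. A single outlying library is argued against, since the list median of the lower DKO library was 0.91 above the WT mean, against a range of 0.34 between the WT libraries. Of these members, 6 also stand in another list. A larger share of regulatory T cells in the sort could raise Foxp3, Il2ra, Ikzf2 and Ctla4 together. The first 3 lay higher in both DKO libraries while Ctla4 had a log2 fold change of 0.05, and the sort excluded CD25-positive cells, so a CD25-negative share and a change within naive cells cannot be told apart from bulk counts.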

How the results depend on the processing

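The polymerase III scaling, the trend removals, edgeR's newer default, the test of protein-coding genes alone, the ratio to single polymerase III RNAs and the lists without the targets were tests chosen only after the results had been seen. Btg1 and Btg2 were called in all settings tried on genes or transcripts, with log2 fold changes from −3.32 to −6.50 and from −1.90 to −8.23. Their smallest sizes came from log2(TPM + 1), which compresses low values. Counts of other genes depended on the test and its settings. Against 7 higher and 9 lower, there were 194 and 66 with total counts only, 141 and 254 without a count filter, 12 and 24 at a mean of at least 5 CPM, 55 and 133 by DESeq2, and 12 and 26 by voom. On log2(TPM + 1) there were 1 and 4, on log2(TPM + 0.1) 1 and 5, with the effective length offset 2 and 4, and at a threshold of 0.1 18 and 25. Scaled to the polymerase III transcripts there were 472 and 22, with edgeR's newer default 11 and 17, with the length trend removed 23 and 27, with the GC trend removed 3 and 3, and with protein-coding genes only 35 and 16. Among protein-coding genes RLE factors gave 7 higher and 3 lower and upper-quartile scaling 8 and 3. Upper-quartile scaling gave 14 lower. The planned older edgeR default was the installed one and so the test itself. With 27379 transcripts as units, edgeR called 0 genes higher and 2 lower (716 and 653 transcripts at an unadjusted p below 0.05). Leaving out each library in turn gave 12 to 34 higher and 28 to 131 lower, where a group of 1 is assumed to vary like the other. The cause was not tested. Ms4a4c also lost its call with thinned counts (log2 1.62, adjusted p = 0.0535 by edgeR, over a range of 0.73 to 2.59 in log2 fold change).

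The replicate number of the titles was also fitted as a replicate block, which gave 53 higher and 89 lower, or 52 and 143 with the length offset, on 1 residual degree of freedom. Deviations of same-numbered libraries from their group means correlated at −0.316 across all genes and −0.219 across protein-coding genes. The labels do not say that the number marks a pair of mice, so the libraries share only a number.

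Lists past the threshold numbered 11 higher and 3 lower. There were 18 higher on log2(TPM + 1), 5 lower at a mean of at least 5 CPM, 4 to 14 higher and 3 to 6 lower when each library was left out, 0 and 0 with an estimated correlation, and 0 higher and 1 lower by fry. The regulatory T cell, cytosolic ribosomal protein and mitochondrially encoded lists kept their calls in each other setting. The JAK-STAT list lost its call by camera with the offset (adjusted p = 0.0733), the block (0.0561), both (0.113), polymerase III scaling (0.0615), the length trend removed (0.0586) and protein-coding genes only (0.0845). The effector list lost it with total counts (relative median 0.195, adjusted p = 0.225), log2(TPM + 1) (0.034, 0.269) and log2(TPM + 0.1) (0.125, 0.132). By camera, calls also ended for the naive list with the offset (0.0513), block and offset (0.0894) and protein-coding genes only (0.0817), and for the anergy list in both TPM fits (0.11 and 0.0540) and with the offset (0.0513). Others were S phase on log2(TPM + 1) (relative median 0.009, adjusted p = 0.104), TCR signalling with block and offset (0.0557), cholesterol on log2(TPM + 1) (0.0505) and with block and offset (0.0894), and CD8 T cells without a count filter (0.0564). The protein-coding share differed by 7.35 percentage points, or 4.90 to 9.81 when each library was left out and 9.52 for all genes annotated protein-coding. The log2 ratio of protein-coding to polymerase III counts differed, DKO minus WT, by 1.20 against Rmrp alone, 1.06 against Rn7sk, 0.763 against Rn7s1 and 0.868 against Rpph1. Over named genes, 1614 comparisons with an alternative kept direction and side of the threshold, 183 gained a call, 27 lost one and 64 changed sign. Over lists these counts were 930, 42, 62 and 89. Signs are compared even where neither value passed the threshold, and a list's value is its median relative to all tested genes. The causes of these sign changes were not tested. Over all genes, edgeR also called Btla (log2 0.89), Trp53inp1 (0.91), Ifngr1 (0.72), Ctsw (1.14), Rpl12 (−1.01), Rpl5 (−1.31), Rpl31 (−0.78), Snhg17 (−1.32) and Gas5 (−0.71) without WT replicate 1, Ctsw (1.25) and mt-Nd6 (−1.14) without WT replicate 2, and Top2a (1.73) and Mki67 (2.67) without DKO replicate 1.

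Of the named genes that changed sign, log2 fold changes were as follows. Scaled to the polymerase III transcripts, values were Klf6 0.256, Rpl31 0.281, Rps18 0.221, mt-Nd3 0.357, mt-Nd5 0.19, mt-Nd2 0.137, Gas5 0.378, Cnot7 0.703, Foxo1 0.892, Tcf7 0.824, Myc 0.875, Ighm 0.893, Rora 0.473, Bpgm 0.916 and Pecam1 0.773. With transcripts as units, values were Gas5 0.088, Foxp1 −0.451, Myc 0.095, Bpgm 0.003 and Pecam1 0.182. With total counts only, values were Cnot7 0.119, Foxo1 0.306, Tcf7 0.223, Myc 0.272, Ighm 0.293, Bpgm 0.316 and Pecam1 0.214. On log2(TPM + 1), values were Cnot7 0.285, Foxo1 0.22, Tcf7 0.285, Myc 0.199, Ighm 0.309, Bpgm 0.088 and Pecam1 0.15. On log2(TPM + 0.1), values were Cnot7 0.46, Foxo1 0.324, Tcf7 0.291, Myc 0.27, Ighm 0.337, Bpgm 0.228 and Pecam1 0.181. With the effective length offset, the value was Cnot7 0.005. With the replicate block and length offset, the value was Cnot7 0.112. With the length trend removed, the value was Cnot7 0.063. With factors from protein-coding genes, the value was Klf2 −0.021. At a mean of at least 5 CPM, the value was Klf2 −0.002. With protein-coding genes only, the value was Klf2 −0.018. Without a count filter, the value was Bpgm 0.00.

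Of the lists that changed sign, relative medians were as follows. On log2(TPM + 1), values were BTG-TOB 0.069, immediate early 0.055, G1 cyclins 0.00, GIMAP GTPases 0.22, translation factors 0.054, ribosome biogenesis 0.122, splicing factors 0.19, OXPHOS 0.139, variable segments 0.076, B cells −0.041, myeloid cells −0.003 and erythroid cells 0.00. On log2(TPM + 0.1), values were BTG-TOB 0.046, immediate early 0.02, GIMAP GTPases 0.085, ribosome biogenesis 0.103, splicing factors 0.09, OXPHOS 0.05 and variable segments 0.117. At a mean of at least 5 CPM, values were mRNA decay −0.024, G1 cyclins −0.012, mTORC1 −0.009 and variable segments 0.167. With thinned counts, values were mRNA decay −0.023, splicing factors 0.002, unfolded protein response −0.008, Zfp genes 0.002 and variable segments 0.00. With the length trend removed, values were mRNA decay 0.00, G1 cyclins −0.002, ribosome biogenesis 0.005, OXPHOS 0.004 and variable segments 0.195. With the GC trend removed, values were mRNA decay −0.014 and Zfp genes 0.023. With protein-coding genes only, values were mRNA decay −0.029, G1 cyclins −0.021 and interferon −0.011. With the effective length offset, values were ribosome biogenesis 0.037, tRNA synthetases −0.002 and variable segments 0.071. With the replicate block and length offset, values were ribosome biogenesis 0.014, tRNA synthetases −0.01 and variable segments 0.07. Scaled to the polymerase III transcripts, values were ribosome biogenesis 0.00, variable segments 0.019 and erythroid cells 0.012. Without a count filter, values were splicing factors 0.018, Zfp genes 0.025 and myeloid cells −0.064. With the replicate block, values were Zfp genes 0.004 and erythroid cells 0.15. With voom, the value was erythroid cells 0.187.

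Leaving out each library in turn gave log2 fold changes of Runx3 −0.014 to 0.282, Klf2 −0.169 to 0.237, Foxp1 −0.023 to 0.235, Foxo1 −0.102 to 0.03, Tcf7 −0.312 to 0.104, Myc −0.255 to 0.129, Ighm −0.235 to 0.164, Ctss −0.166 to 0.289, Rora −0.784 to 0.19, Bpgm −0.179 to 0.127 and Pecam1 −0.251 to 0.021. Relative list medians ranged over BTG-TOB −0.03 to 0.034, mRNA decay −0.056 to 0.061, immediate early −0.026 to 0.06, interferon −0.232 to 0.40, GIMAP GTPases −0.108 to 0.068, translation factors −0.147 to 0.008, ribosome biogenesis −0.111 to 0.153, tRNA synthetases −0.278 to 0.304, proteasome −0.117 to 0.221 and splicing factors −0.059 to 0.029. For the other lists they ranged over OXPHOS −0.311 to 0.173, glycolysis −0.108 to 0.156, mTORC1 −0.033 to 0.147, unfolded protein response −0.091 to 0.119, heat shock proteins −0.028 to 0.298, Zfp genes −0.058 to 0.021, histones −0.19 to 0.345, variable segments −0.206 to 0.217, B cells −0.165 to 0.663 and erythroid cells −0.204 to 0.017. Of simulated genes, edgeR recovered 52.9% at a log2 change of 1 and 95.5% at 2, and thinning to the smallest library left 6 higher and 9 lower.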

Other observations

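The test on histones was chosen only after the result was seen, and the single genes named here were chosen after their values were seen. Immediate early and activation genes moved both ways. Of 46 tested members, 6 were higher and 4 lower adjusted over the list alone and 0 over all genes by edgeR, and the median was −0.08 (camera adjusted p = 0.884). The lower ones included Junb, an AP-1 subunit, at 522 and 608 against 328 and 228 CPM, the ERK phosphatase gene Dusp5 (log2 −0.93) and the NF-κB inhibitor gene Tnfaip3 (−0.75). The higher ones included Cd44, Tnfrsf4, encoding the costimulatory receptor OX40 (1.31), Egr2 and Egr3, targets of antigen receptor signals (0.93 and 0.997), and Dusp6 (0.82).

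Samd9l, an interferon-induced gene, was at 82.7 and 84.3 CPM in WT and 45.7 and 41.5 CPM in DKO (log2 −0.94, adjusted p = 0.0534 by edgeR). The chaperone genes Hspa1a and Hspa1b were high in DKO replicate 1 alone, at 3.37 and 14.4 against 144 and 16.7 CPM and at 7.32 and 43.0 against 261 and 31.1 CPM.

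If BTG1 and BTG2 acted mainly on mRNAs with long 3′ UTRs, fold changes could rise with 3′ UTR length. Spearman's rho was 0.005 across 10235 of 10720 protein-coding genes (95.5%), which are not independent replicates. The same rho was −0.235 between the WT and 0.136 between the DKO libraries. By the bound set beforehand, no trend beyond those within groups was seen. A trend with genotype no larger than those could be hidden by them, so the test cannot exclude one. Against whole transcript length, rho was 0.06 for DKO minus WT, −0.234 between the WT and 0.132 between the DKO libraries. The trends within groups are thus not particular to 3′ UTRs. If mRNAs without a poly(A) tail gained less, histone mRNAs could lie below other genes in DKO. Their median log2 fold change was 0.09 over 55 genes, at −0.17 and 0.29 in the DKO libraries and −0.21 and 0.21 in WT, so the test leaves this open.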
